A study of Macaca fascicularis with 30 samples.

How the data were processed

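Single-nucleus RNA was measured in 19 libraries of the dorsolateral prefrontal cortex of female cynomolgus macaques, spatial RNA in 8 Visium sections, and single-cell RNA in 3 further prefrontal libraries, 30 samples in all. The deposited matrices hold raw UMI counts per gene and barcode, without normalization, per the file headers and the values. The headers of the nuclei and the single prefrontal libraries give software version 3.1.0 and those of the sections spaceranger 1.1.0. The series text names Cell Ranger 2.1.0, a version 2 kit and a NovaSeq 6000, the extract protocol a version 3.1 kit, and the processing notes CASAVA 1.8. These statements differ and were left as they stand. The genome build and aligner are not given in the sources used here. The matrices share 22310 genes, of which 5956 have no symbol, 8 symbols occur more than once and 13 genes are mitochondrial. Gene identifiers are the Ensembl identifiers in the files.

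Barcodes with at least 500 UMIs, at least 300 genes and at most 5% mitochondrial UMIs were kept, and doublets called by Scrublet per library were removed (Python 3.11.15, scanpy 1.11.5, numpy 2.4.6, scipy 1.17.1). Of 146893 barcodes, 3867 were over the mitochondrial limit and 6049 were called doublets, which left 136977. Clusters were named from fixed marker sets, so classes are called excitatory-like and so on, and 4456 nuclei stayed unnamed, 4238 of them in a single cluster. The neighbour search behind the clusters depends on processor settings, which were fixed. Other settings, under which the choices named below as made after seeing the data were made, gave other clusters, and some list calls and the libraries that decide the call of CCNJL changed with them. For the sections, spots with at least 500 UMIs were clustered, and clusters led by oligodendrocyte markers formed the region led by myelin genes. In the single prefrontal libraries, clusters with at least 2 leading genes of blood or border immune cells were left unnamed.

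Counts were summed per library and class, and a library entered a class with at least 10 nuclei. All 3 groups were fitted together with edgeR 4.0.16 (TMM normalization, filterByExpr, robust quasi-likelihood test; R 4.3.3, limma 3.58.1), and genes were called at a Benjamini-Hochberg adjusted p under 0.05 per class and contrast. Fold changes are edgeR log2 fold changes, with standard errors from the same fit. DESeq2 1.42.0 was run beside it. Values in CPM (UMI counts scaled to a common library total) are means over libraries. Gene lists, 28 in number, were tested with camera at a preset correlation of 0.01, where at least 5 members were measured, which gave 171 tests per contrast. Camera with an estimated correlation, fry, and an exact two-sided permutation test of a list score per library stand beside it. Shares of nuclei were compared by exact two-sided permutation tests over all regroupings, adjusted over 27 tests. Shares in the single prefrontal libraries carry 95% exact Clopper-Pearson intervals. The recovery of known changes was tested on simulated data.

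The tests, gene lists, markers and the rule for named genes were set before the data were examined. The rule takes called genes with a mean log2 CPM of at least 4, and the 2 genes with the smallest p, given as not passing, where a class has no called gene. Members of lists are given as examples by small p, and these, the genes named for DESeq2 or for other settings, and SHCBP1 were chosen after their values were seen. Also chosen after seeing the data were the naming rule for clusters in its final form, the minimum of 5 list members, the blood gene rule, the 3 doubted libraries (HC5, DL3 and DL5) and the permutation of list scores. The same holds for the fits without neuron clusters that have a single foreign marker among their leading genes. It also holds for sections 6 and 7 alone, a region needing at least 2 markers, list scores without single libraries, and the single prefrontal libraries without a mitochondrial limit. Differences in list scores without 1 library are given where they moved by over 1.5 times. Counts of subclass genes in RES against HC and DL against RES and of genes in fibroblast-like nuclei were also added after their values were seen, and were not run with 1 library left out or with other splits.

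The alternatives tried were DESeq2 size factors, DESeq2, no filter on low counts, a fit of only the groups compared, the replicate number as a block, the median UMI count as a covariate, doublets kept, at least 2000 UMIs, genes far higher in another class left out, and each library left out in turn. Splits of the samples were limited to 50 per class and 25 for subclasses because of run time. Depth per library is given with the report. Intervals of single libraries cover counting error only.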

Results

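Nuclei from the dorsolateral prefrontal cortex, a frontal region involved in working memory and emotional control, were profiled after death in female cynomolgus macaques (Macaca fascicularis). The labels place 7 nuclei libraries in a healthy control group (HC), 7 in a depressive-like group (DL) and 5 in a group called resilient in low social rank (RES). The series text gives as many animals as nuclei libraries in each group, so each library was taken as an animal. Total depth ran from 43549247 UMIs (unique molecular identifiers, which count captured RNA molecules) in HC5 to 82289845 in HC4, and the median barcode held between 3829.5 UMIs in HC5 and 9224 in HC4. Visium sections, in which barcoded spots capture RNA over small regions of tissue, came from 3 HC, 3 RES and 2 DL samples and held 22897861 to 44947197 UMIs each. A further 3 prefrontal libraries, 1 per group, held 19364512 UMIs (HC), 23942269 (RES) and 21086644 (DL). Of 146893 barcodes in the nuclei libraries, 136977 were kept, and 132521 of these (96.7%) fell in clusters that could be named from fixed markers.

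The cellular make-up of the cortex was compared first. Excitatory-like nuclei were the most numerous class, at 49.1% ± 4.63 of named nuclei in HC (SD, n = 7), 49.4% ± 2.75 in RES (n = 5) and 48.8% ± 4.08 in DL (n = 7). Inhibitory-like nuclei made up 20.7% ± 2.01, 19.7% ± 1.81 and 19.6% ± 2.70 in HC, RES and DL, and oligodendrocyte-like nuclei 15.4% ± 3.48, 16.4% ± 2.17 and 15.9% ± 4.50. Astrocyte-like nuclei ranged from 1.90% in DL2 to 9.77% in HC4. The share of microglia-like nuclei was 3.59% ± 0.487 in HC, 3.54% ± 0.403 in RES and 3.34% ± 1.03 in DL. T cell-like nuclei stood at 0.184% ± 0.104 in HC against 0.860% ± 1.34 in DL, a difference of 0.676 percentage points. It did not pass the correction (exact two-sided permutation test, p = 0.0198, adjusted p = 0.535). DL5 alone held 3.88%, and the difference was 0.173 percentage points without it and 0.0591 with at least 2000 UMIs per nucleus. T cell-like nuclei are small in UMI count, at 0.191 of the library median. The limit of 2000 UMIs thus removes much of the class itself, and the smaller difference under it cannot test the group difference. Fibroblast-like nuclei were at 1.02% ± 0.507 in HC and 2.60% ± 1.75 in DL (exact permutation p = 0.0507, adjusted p = 0.614). Across 9 classes and 3 contrasts, 0 of 27 shares differed past an adjusted p of 0.05 in the exact permutation test.

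**Figure D1:**
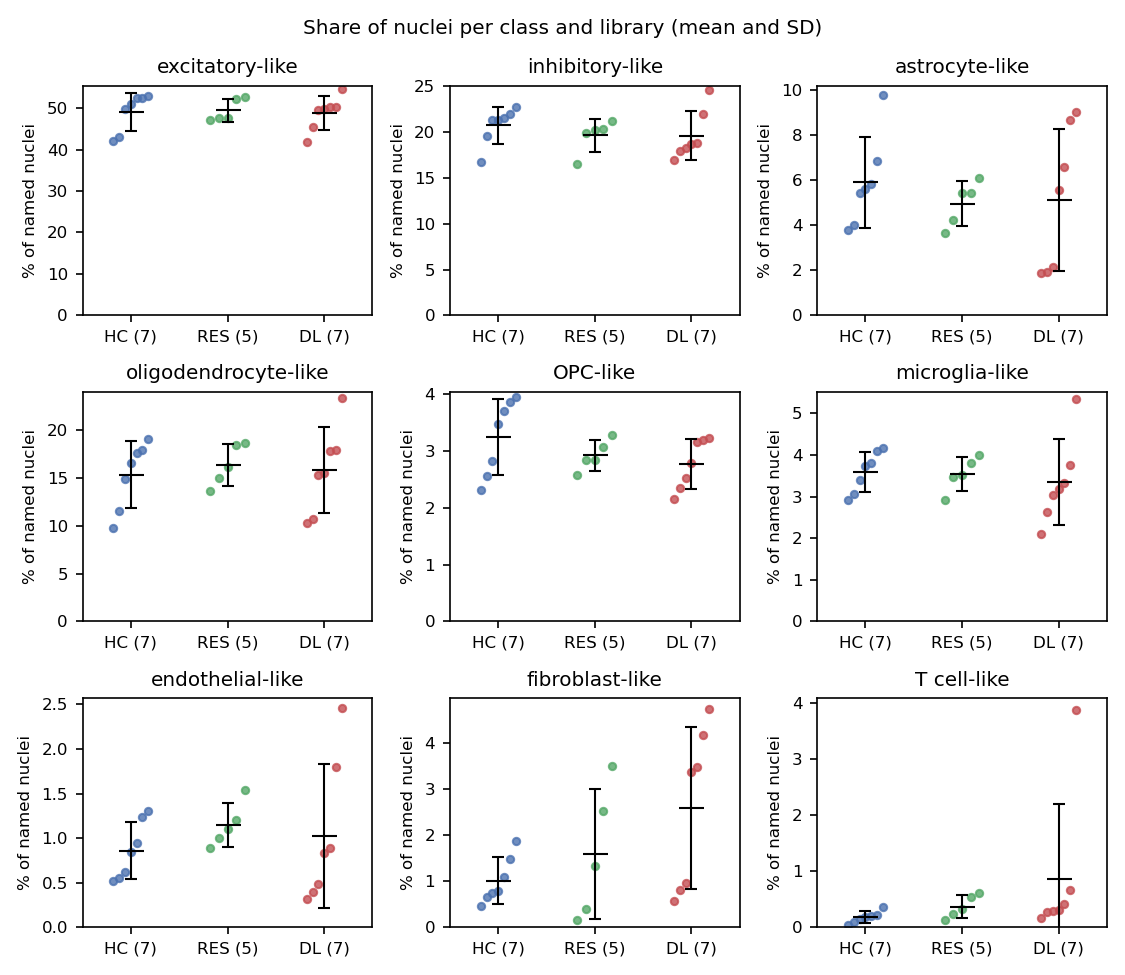
Share of named nuclei (percent, vertical axis) for 9 classes, with a point per library, horizontal bars at the group means and error bars of 1 SD, for 7 HC, 5 RES and 7 DL libraries. The groups overlap in every class shown, and the T cell-like share of 3.88% in DL5 lies apart from the other DL libraries.

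The comparison of DL with HC asks how the depressive-like state goes with expression in each cell class. In excitatory-like nuclei, all 19 measured immediate early genes, which neurons switch on within minutes of activity, had lower estimates in DL (median log2 fold change -0.45, camera adjusted p = 5.9e-08, and adjusted p = 0.483 with an estimated correlation). Among them were ARC, a regulator of synaptic receptors, at a log2 fold change of -0.62 (SE 0.25), the dual-specificity phosphatases DUSP5 at -0.48 (SE 0.17) and DUSP6 at -0.56 (SE 0.24), and FOSB at -0.44 (SE 0.19). Glucocorticoid-response genes were lower for 11 of 15 members (median -0.16, camera adjusted p = 0.00290, and adjusted p = 0.442 with an estimated correlation). ERRFI1, a feedback inhibitor of EGF receptors that is on this list, averaged 19.8 ± 2.56 CPM in HC and 14.8 ± 1.87 in DL (SD, n = 7 each; edgeR log2 fold change -0.42, SE 0.10, adjusted p = 0.732, below the HC mean in 7 of 7 libraries). KLF10, a zinc-finger transcription factor, averaged 8.54 ± 1.96 CPM in HC and 5.25 ± 0.849 in DL (edgeR log2 fold change -0.70, adjusted p = 0.732). Monoamine receptor genes had lower estimates for 15 of 18 members (median -0.26, camera adjusted p = 0.0189, and adjusted p = 0.483 with an estimated correlation). The dopamine receptor gene DRD3 among them was at -0.64 (SE 0.29). In HC5, 1597 nuclei lay in an excitatory-like cluster of which that library made up 88.7%, so excitatory-like values in HC5 came in part from a cluster that other libraries hardly held.

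Inhibitory-like nuclei gave lower estimates in DL for all 16 measured immediate early genes (median log2 fold change -0.30, camera adjusted p = 0.000155, and adjusted p = 0.525 with an estimated correlation). FOS was at -1.21 (SE 0.39) and ARC at -0.58 (SE 0.28). Heat shock and chaperone genes, whose products refold damaged proteins, were lower for 13 of 14 members there (median -0.24, camera adjusted p = 1.1e-05, and adjusted p = 0.483 with an estimated correlation). DNAJB4 was at -0.44 (SE 0.11), HSPH1 at -0.36 (SE 0.13) and DNAJB1 at -0.54 (SE 0.22). The difference in the mean list score of a library (log2 of CPM + 1) was -0.213, and -0.134 without HC5 and -0.141 without DL4. Glucocorticoid-response genes were lower for 13 of 15 members (median -0.13, camera adjusted p = 0.00827, and adjusted p = 0.442 with an estimated correlation). INVS, which encodes the ciliary protein inversin, was at 58.8 ± 7.69 CPM in HC and 82.2 ± 9.98 in DL (edgeR log2 fold change 0.48, SE 0.09, adjusted p = 0.398, 7 of 7 DL libraries above the HC mean). ATAD2, a chromatin-bound ATPase, was at 21.2 ± 1.58 CPM in HC and 27.6 ± 1.64 in DL (edgeR log2 fold change 0.38, adjusted p = 0.398).

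Heat shock and chaperone genes were lower in DL by the preset camera test in all 7 classes. Their median log2 fold change was -0.20 in excitatory-like, -0.26 in astrocyte-like, -0.27 in oligodendrocyte-like, -0.17 in OPC-like (oligodendrocyte precursor), -0.23 in microglia-like and -0.69 in endothelial-like nuclei, at preset adjusted p-values of 0.000149, 0.00273, 0.00248, 0.00717, 0.00521 and 9.2e-06. With an estimated correlation these 6 classes had an adjusted p of 0.483, 0.685, 0.7098, 0.607, 0.442 and 0.442. All classes come from the same libraries, so a like result in several classes, here or in other comparisons, is not independent support. Without 3 libraries doubted after the data were seen (HC5, DL3 and DL5), the excitatory-like median was -0.07 (camera, adjusted p = 0.0620), the astrocyte-like one -0.16 (adjusted p = 0.088) and the oligodendrocyte-like one -0.09 (adjusted p = 0.0658). The difference in the mean list score went from -0.174 to -0.102 in excitatory-like nuclei without HC5, from -0.228 to -0.147 in oligodendrocyte-like nuclei without DL4 and from -0.459 to -0.708 in endothelial-like nuclei without HC3.

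In microglia-like nuclei, 7 of 8 measured antigen presentation genes had higher estimates in DL (median log2 fold change 0.99, camera adjusted p = 2.6e-06, and adjusted p = 0.442 with an estimated correlation). Examples by small p came from MHC class II, which displays peptides to T cells and was not tested as a list of its own. HLA-DRA was at 2.93 (SE 0.60), HLA-DPA1 at 2.66 (SE 0.60) and the invariant chain CD74 at 2.21 (SE 0.49). Each had an adjusted p of 0.189 or 0.225 by edgeR over all genes and of 0.000711 adjusted over the list alone. Mean CD74 was 90.4 CPM in HC and 407 CPM in DL. MHC genes belong to a multigene family, so reads may be split between near-identical copies. CPVL, a carboxypeptidase of myeloid cells, was at 3.72 ± 5.04 CPM in HC and 66.0 ± 68.3 in DL (edgeR log2 fold change 4.08, SE 0.80, adjusted p = 0.189, 6 of 7 DL libraries above the HC mean). P3H2, a collagen prolyl hydroxylase, was at 38.7 ± 23.7 CPM in HC and 103 ± 11.4 in DL (edgeR log2 fold change 1.40, SE 0.27, adjusted p = 0.189, 7 of 7 DL libraries above the HC mean). Activated microglia genes were higher for 12 of 15 members (median 0.17, camera adjusted p = 0.0242, and adjusted p = 0.961 with an estimated correlation). The list named for reactive astrocytes was higher for 6 of 8 members (median 0.30, camera adjusted p = 0.0163, and adjusted p = 0.483 with an estimated correlation). Among them were the cytoskeletal gene VIM at 1.45 (SE 0.37) and the adhesion receptor CD44 at 1.56 (SE 0.55). DL5, with the highest T cell-like share, also had the highest antigen presentation score in microglia-like nuclei, 2.01. In excitatory-like nuclei 8 of 11 antigen presentation genes were higher (median 0.59, camera adjusted p = 0.000805, and adjusted p = 0.442 with an estimated correlation), at low levels such as 0.635 CPM of HLA-DRA in DL against 264 CPM in microglia-like nuclei, and the difference in the mean list score went from 0.256 to 0.157 without DL5.

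**Figure D2:**
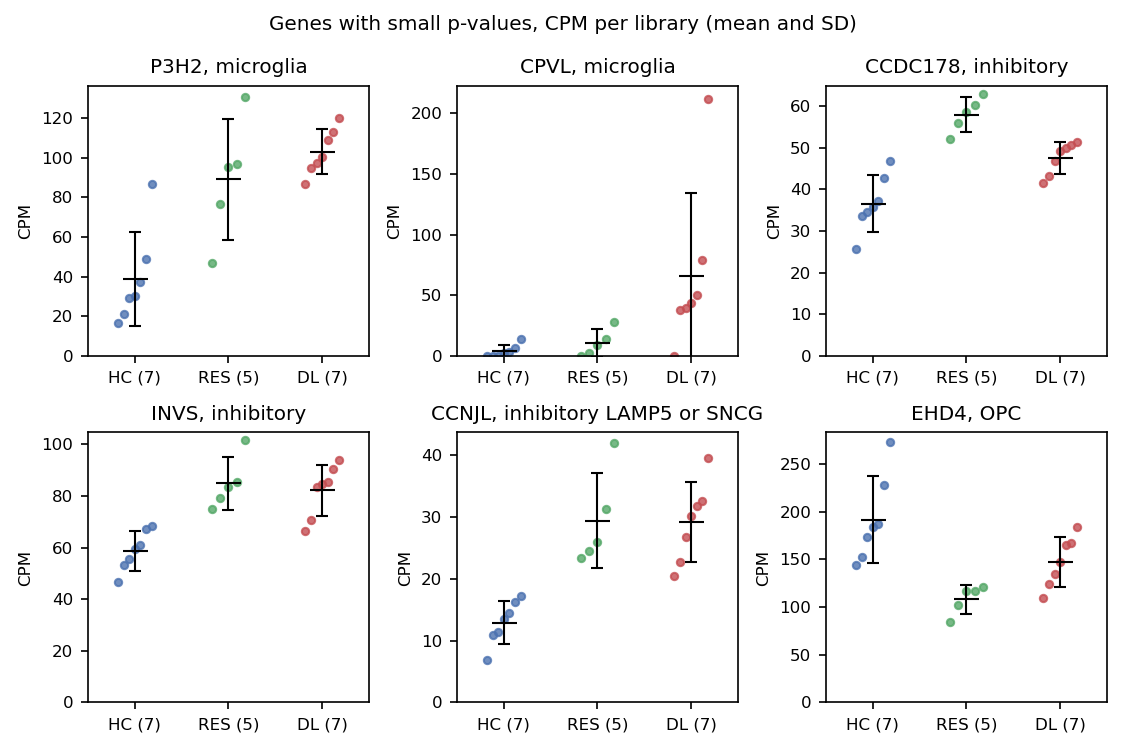
Expression in CPM (UMI counts scaled to a common library total, vertical axis) of 6 genes with small p-values, with a point per library, horizontal bars at the group means and error bars of 1 SD, for 7 HC, 5 RES and 7 DL libraries. Only CCNJL in DL against HC passed the correction within its subclass, and CPVL in DL libraries spreads widely around its mean of 66.0.

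In endothelial-like nuclei, which line blood vessels, all 8 measured immediate early genes had lower estimates in DL (median log2 fold change -0.88, camera adjusted p = 0.000155, and adjusted p = 0.442 with an estimated correlation). FOS was at -2.69 (SE 1.12). Genes of the NF-kB and cytokine response were lower for 6 of 7 members (median -0.61, camera adjusted p = 0.00240, and adjusted p = 0.442 with an estimated correlation), among them the inhibitor NFKBIA at -0.95 (SE 0.25) and the interleukin receptor IL1R1 at -1.15 (SE 0.49). Cholesterol synthesis genes were lower for 7 of 7 members there (median -0.47, camera adjusted p = 0.0429, and adjusted p = 0.685 with an estimated correlation), a call that ended without the 3 doubted libraries (median -0.25, adjusted p = 0.595). In oligodendrocyte-like nuclei, by contrast, 14 of 19 cholesterol synthesis genes had higher estimates (median 0.14, camera adjusted p = 0.00273, and adjusted p = 0.483 with an estimated correlation). INSIG1 was at 0.72 (SE 0.17) and the regulator SREBF2 at 0.31 (SE 0.10). The difference between these classes was not tested. HC5 had the highest oligodendrocyte-like cholesterol score of the HC libraries, 0.425, and without it the difference in the mean score went from 0.161 to 0.246. Glucocorticoid-response genes in oligodendrocyte-like nuclei were lower for 14 of 15 members (median -0.25, camera adjusted p = 0.00273, and adjusted p = 0.442 with an estimated correlation). ERRFI1 was at -0.67 (SE 0.17).

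Genes with the smallest p-values in the remaining classes did not pass either. In astrocyte-like nuclei ESF1 had an edgeR log2 fold change of 0.58 (SE 0.14) and EPHX2, which hydrolyses fatty acid epoxides, of -0.71 (SE 0.17), each with an adjusted p of 0.865. CCDC175 in oligodendrocyte-like nuclei was at -1.02 (SE 0.20, edgeR adjusted p = 0.584) and ANLN, which encodes the actin-binding protein anillin, at -0.61 (SE 0.14, adjusted p = 0.794). In OPC-like nuclei MCMDC2 was at -0.67 (SE 0.15, edgeR adjusted p = 0.774) and CREM, a cAMP-responsive transcription factor, at -0.98 (SE 0.23, adjusted p = 0.912). Endothelial-like nuclei gave ICA1 at 0.84 (SE 0.16, edgeR adjusted p = 0.133) and ULK4, a kinase-family gene, at 0.75 (SE 0.17, adjusted p = 0.274).

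By edgeR's quasi-likelihood test, 0 genes passed an adjusted p of 0.05 in DL against HC in each of the 7 classes. Fibroblast-like nuclei, an eighth class fitted with 6641 genes, had 0 genes passing in each of the 3 contrasts, and DESeq2 called DPYD there in DL against HC (log2 fold change 0.75, adjusted p = 0.00319). At an unadjusted p under 0.05 there were 990 of 16606 genes in excitatory-like, 788 of 14687 in inhibitory-like, 607 of 10684 in astrocyte-like, 631 of 11696 in oligodendrocyte-like, 378 of 8472 in OPC-like, 400 of 7614 in microglia-like and 448 of 6079 in endothelial-like nuclei. DESeq2 called 0, 9, 0, 1, 1, 8 and 1 genes in the same order, and its microglia-like calls were all higher in DL and included P3H2, CPVL, CD74, HLA-DPA1, HLA-DRA and TRPS1. With 1 library left out edgeR called 1 gene in excitatory-like nuclei without DL1 (KHDC1L), 1 in microglia-like nuclei without HC6 (P3H2) and 1 in endothelial-like nuclei without DL2 (ICA1), and P3H2 also passed with no filter on low counts. GALNTL6, a glycosyltransferase-family gene, was at 1.20 (SE 0.30, edgeR adjusted p = 0.912) in OPC-like nuclei, and at 1.21 (adjusted p = 0.000666) with the replicate number as a block, and it was the OPC-like call of DESeq2. Over the 171 tests of lists by class, camera with its preset correlation called 31 (8 higher, 23 lower) and 58 without the 3 doubted libraries, while the estimated correlation, fry and an exact permutation test of list scores per library each called 0. Among the members of the lists, 0 were called over all genes and 28 adjusted over the list alone.

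**Figure D3:**
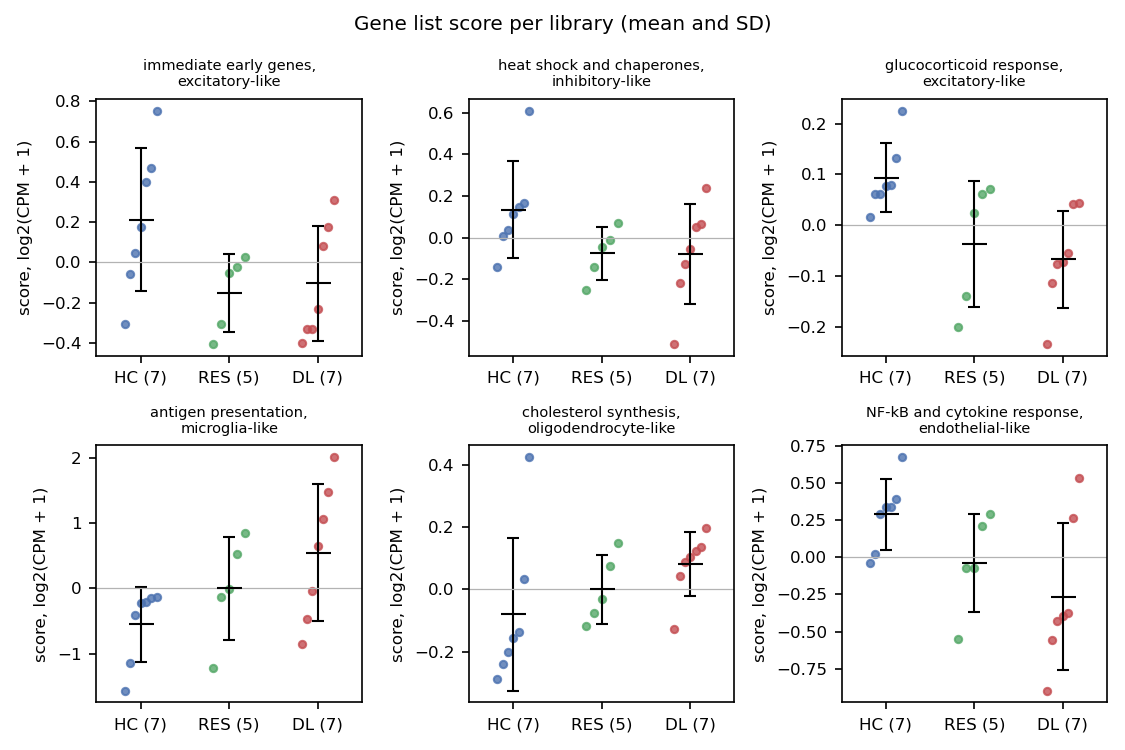
Mean score of 6 gene lists per library (log2 of CPM + 1, centred per gene, vertical axis), with horizontal bars at the group means and error bars of 1 SD, for 7 HC, 5 RES and 7 DL libraries. Scores of single libraries overlap between groups in every panel, for example from -0.85 to 2.01 in DL for antigen presentation in microglia-like nuclei.

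Neurons were also compared by subclass, to ask whether DL and HC differ within a layer or interneuron type. CCNJL (ENSMFAG00000002131), which encodes a cyclin J-like protein, was higher in DL in inhibitory-like nuclei of the LAMP5 or SNCG subclass, at 12.9 ± 3.54 CPM in HC and 29.1 ± 6.44 in DL (SD, n = 7 each; edgeR log2 fold change 1.18, SE 0.19, adjusted p = 0.0200, 7 of 7 DL libraries above the HC mean). RES libraries were at 29.4 ± 7.62 CPM. It was the only gene called in DL against HC among 11 subclasses, which together had 6209 of 128182 gene tests at an unadjusted p under 0.05. Each correction covered the genes of 1 subclass only, 11719 in the LAMP5 or SNCG subclass. The call of CCNJL thus holds within its subclass and was not corrected over the 128182 gene tests of all 11 subclasses. DESeq2 called 6 genes in all, corrected in the same way. In RES against HC edgeR called 0, with 6008 of 128182 gene tests at an unadjusted p under 0.05. CCNJL was at an edgeR log2 fold change of 1.18 (SE 0.20, adjusted p = 0.0558) in the same subclass. It passed there with DESeq2 size factors (adjusted p = 0.0474), with no filter on low counts (0.0122) and without the 3 doubted libraries (0.0482), and DESeq2 made 22 calls of 14 genes over the subclasses in RES, CCNJL among them (adjusted p = 0.000317). DL against RES gave 0 by either tool. In DL against HC the adjusted p of CCNJL rose to 0.0987 without the 3 doubted libraries. It lay between 0.0544 and 0.0929 without HC4, HC6, HC7, DL1, DL2, DL5 or DL6, left out 1 at a time, at log2 fold changes of 1.097 to 1.20.

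RES was compared with HC to ask what goes with low social rank in animals labelled resilient. As in DL, all 19 immediate early genes had lower estimates in excitatory-like nuclei (median log2 fold change -0.55, camera adjusted p = 6.4e-08, and adjusted p = 0.697 with an estimated correlation). ARC was at -0.76 (SE 0.28), FOS at -1.11 (SE 0.46) and EGR3 at -0.54 (SE 0.21). Inhibitory-like nuclei had 15 of 16 of these genes lower (median -0.31, camera adjusted p = 0.000805, and adjusted p = 0.7101 with an estimated correlation). Heat shock and chaperone genes were lower for all 15 members in excitatory-like nuclei (median -0.27), 14 of 14 in inhibitory-like (-0.26), 14 of 15 in astrocyte-like (-0.34), 15 of 15 in oligodendrocyte-like (-0.25) and 10 of 11 in endothelial-like nuclei (-0.52). Their preset camera adjusted p-values were 0.000301, 9.2e-05, 0.000301, 0.000301 and 0.000301, against adjusted p-values of 0.69998, 0.697, 0.697, 0.69998 and 0.697 with an estimated correlation. Without HC5 the difference in the mean list score went from -0.188 to -0.115 in excitatory-like and from -0.2097 to -0.130 in inhibitory-like nuclei, and in endothelial-like nuclei it went from -0.327 to -0.575 without HC3 and to -0.166 without RES3. DNAJA1 in astrocyte-like nuclei was at 32.2 ± 6.69 CPM in HC and 18.0 ± 1.64 in RES (edgeR log2 fold change -0.83, SE 0.20, adjusted p = 0.929, 5 of 5 RES libraries below the HC mean).

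Genes of the unfolded protein response, which relieves the endoplasmic reticulum of misfolded proteins, were lower in RES for 12 of 14 members in OPC-like nuclei (median log2 fold change -0.29, camera adjusted p = 0.000377, and adjusted p = 0.697 with an estimated correlation). SEL1L was at -0.57 (SE 0.15), PDIA4 at -0.998 (SE 0.28) and HSP90B1 at -0.53 (SE 0.20). In oligodendrocyte-like nuclei glucocorticoid-response genes were lower for 12 of 15 members (median -0.35, camera adjusted p = 0.00779, and adjusted p = 0.697 with an estimated correlation). HSD11B1, whose enzyme forms cortisol from cortisone, was at -0.79 (SE 0.28). Endothelial-like nuclei had lower estimates for 6 of 7 cholesterol synthesis genes (median -0.54, camera adjusted p = 0.00372, and adjusted p = 0.697 with an estimated correlation). SQLE, a rate-limiting enzyme of the pathway, was at -1.14 (SE 0.30). Astrocyte-like nuclei had 11 of 17 cholesterol synthesis genes higher (median 0.12, camera adjusted p = 0.0153, and adjusted p = 0.924 with an estimated correlation), with a difference in the mean score of 0.214 that was 0.344 without HC5, 0.135 without RES1 and 0.124 without RES4.

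**Figure D4:**
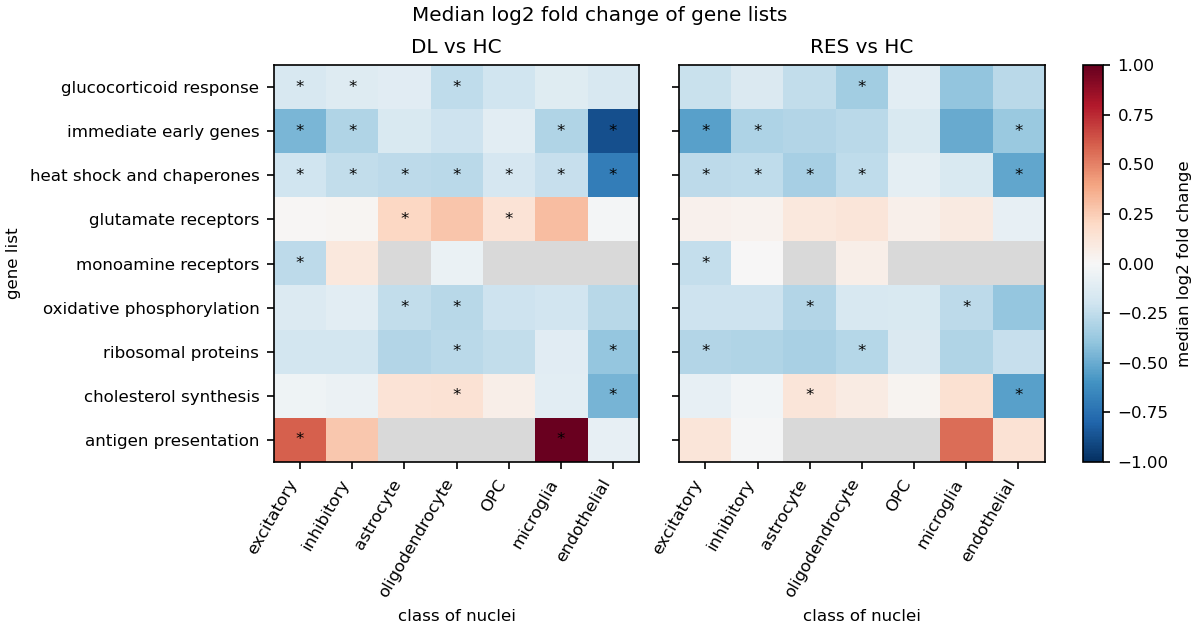
Median log2 fold change (colour) of 9 gene lists in 7 classes of nuclei for DL against HC and RES against HC. Asterisks mark an adjusted p under 0.05 by camera with its preset correlation, grey marks fewer than 5 measured members, and the deepest blue, at -0.88, is for immediate early genes in endothelial-like nuclei of DL.

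Among single genes in RES against HC, CCDC178 (ENSMFAG00000043745) in inhibitory-like nuclei came nearest to the threshold, at 36.6 ± 6.74 CPM in HC and 57.9 ± 4.16 in RES (SD, n = 7 and 5; edgeR log2 fold change 0.66, SE 0.11, adjusted p = 0.0590, 5 of 5 RES libraries above the HC mean). INVS was at 58.8 CPM in HC and 85.1 ± 10.3 in RES in the same class (edgeR log2 fold change 0.53, adjusted p = 0.187). EHD4, which acts in membrane recycling, was at 192 ± 45.2 CPM in HC and 108 ± 15.3 in RES in OPC-like nuclei (edgeR log2 fold change -0.83, SE 0.16, adjusted p = 0.0986, 5 of 5 RES libraries below the HC mean). ABHD2 there was at 0.41 (SE 0.10, adjusted p = 0.712). Endothelial-like FREM2, an extracellular matrix protein gene, was at 104 ± 38.6 CPM in HC and 227 ± 52.5 in RES (edgeR log2 fold change 1.1001, SE 0.22, adjusted p = 0.203, 5 of 5 RES libraries above the HC mean), and ICA1 was at 0.80 (SE 0.17, adjusted p = 0.251). Oligodendrocyte-like nuclei gave SLC9B1 at 0.78 (SE 0.15, edgeR adjusted p = 0.502) and the aldehyde dehydrogenase gene ALDH2 at -0.55 (SE 0.12, adjusted p = 0.631). In microglia-like nuclei P3H2 was at 89.1 ± 30.7 CPM in RES (edgeR log2 fold change 1.17 against HC, SE 0.29, adjusted p = 1.000) and TMEM181 at 0.89 (SE 0.22, adjusted p = 1.000). Excitatory-like ALOXE3 was at 0.60 (SE 0.14) and the exocyst gene EXOC1 at 0.30 (SE 0.07), each with an edgeR adjusted p of 0.870. Astrocyte-like CYP27A1, a sterol hydroxylase gene, was at 0.61 (SE 0.14, edgeR adjusted p = 0.929).

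The edgeR test called 0 genes in RES against HC in each class, with 897, 702, 529, 523, 338, 263 and 306 genes at an unadjusted p under 0.05 in excitatory-like, inhibitory-like, astrocyte-like, oligodendrocyte-like, OPC-like, microglia-like and endothelial-like nuclei. These were 3.45% (microglia-like) to 5.40% (excitatory-like) of the genes tested in a class. DESeq2 called 0, 7, 0, 1, 1, 0 and 2, and CCDC178, INVS, SLC9B1, EHD4, FREM2 and ICA1 were among them. CCDC178 passed with no filter on low counts, with the median UMI count as a covariate, with the replicate number as a block (log2 fold change 0.71, adjusted p = 0.0349), without clusters that have a foreign marker among their leading genes, and without HC1, HC3, HC7 or DL2. EHD4 passed with no filter, without the 3 doubted libraries and without HC5, FREM2 with no filter and without HC2, and P3H2 without HC6. An inhibitory-like gene without a symbol (ENSMFAG00000001777) passed with no filter, with the covariate, and without HC5 or DL2. For lists, camera called 18 of 171 (2 higher, 16 lower) and 39 with the replicate number as a block, while the estimated correlation, fry and the exact permutation of list scores each called 0. Of the members, 0 were called over all genes and 14 adjusted over the list alone.

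DL and RES were set against each other to ask what separates the depressive-like group from the resilient one. Microglia-like nuclei had higher estimates in DL for all 8 antigen presentation genes (median log2 fold change 0.47, camera adjusted p = 0.0330, and adjusted p = 0.991 with an estimated correlation). HLA-DRA was at 2.36 (SE 0.63). The difference in the mean list score was 0.544, and 0.300 without DL5 and 0.238 without RES1. Activated microglia genes had higher estimates for 14 of 15 members (median 0.44, camera adjusted p = 0.0133, and adjusted p = 0.991 with an estimated correlation), and the score difference of 0.378 was 0.231 without DL1 and 0.244 without DL5. The 8 measured astrocyte transport genes in OPC-like nuclei were all higher in DL (median 0.30, camera adjusted p = 0.0491, and adjusted p = 0.675 with an estimated correlation). Of synaptic vesicle genes, 15 of 19 had lower estimates in endothelial-like nuclei (median -0.14, camera adjusted p = 0.0330, and adjusted p = 0.991 with an estimated correlation). DL2 had the lowest score there, -1.20, and without it the score difference went from -0.281 to -0.111. CTSL, a lysosomal protease, was at 8.99 ± 2.95 CPM in RES and 25.9 ± 7.53 in DL in OPC-like nuclei (SD, n = 5 and 7; edgeR log2 fold change 1.49, SE 0.36, adjusted p = 1.000). In astrocyte-like nuclei EPHX2 was at 61.8 ± 7.79 CPM in RES and 39.7 ± 7.09 in DL (edgeR log2 fold change -0.63, SE 0.18, adjusted p = 1.000). MYO3B in inhibitory-like nuclei had an estimate of -1.87 (SE 0.46) over a spread of 77.8 ± 75.6 CPM in RES (adjusted p = 0.999). The complement factor gene CFD in endothelial-like nuclei was at 4.04 (SE 1.0015, edgeR adjusted p = 1.000), with 21.9 ± 39.1 CPM in RES and 381 ± 308 in DL, where DL7 was at 0. Without RES2, at 91.6 CPM, the CFD estimate was 6.17 (adjusted p = 0.713). SLC7A6, an amino acid transporter gene, was at -0.81 (SE 0.19, adjusted p = 0.999) in microglia-like nuclei.

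By edgeR, 0 genes passed in DL against RES in every class, with 248, 260, 222, 228, 218, 194 and 125 genes at an unadjusted p under 0.05 in the class order used above. These were 1.49% (excitatory-like) to 2.57% (OPC-like) of the genes tested in a class, and DESeq2 also called 0 in each. Of the list tests, 4 of 171 passed with the preset correlation (3 higher, 1 lower), 25 without the 3 doubted libraries and 10 with the replicate number as a block, and 0 with the estimated one, with fry or with the exact permutation of list scores. Of the members, 0 were called over all genes and 3 adjusted over the list alone.

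Fold changes of DL and of RES against HC were then compared gene by gene, with the caution that both use the same HC libraries and that genes are not independent replicates. Across 7598 genes in excitatory-like nuclei they correlated at r = 0.763 with a covariance of 0.0177. Simulations that redrew every library, HC included, without group differences gave r = 0.454 and a covariance of 0.0105 on average. Each gene was drawn independently there, so covariation between genes within a library was absent. The simulated ranges are thus likely too narrow, and a value outside them does not by itself show a shared response. With the HC libraries split into separate sets for the contrasts, r was 0.0362, above the -0.0235 to 0.0255 of the simulations, while the covariance of 0.000807 lay within their -0.000802 to 0.000913. The covariance in inhibitory-like nuclei lay within the simulated range as well, at 4.6e-06. The same split gave covariances above the simulated range of 0.00626 in oligodendrocyte-like nuclei (simulated -0.00188 to 0.00207), 0.00969 in microglia-like (-0.00278 to 0.00283), 0.0134 in endothelial-like (-0.00373 to 0.00284) and 0.00390 in astrocyte-like nuclei (-0.00221 to 0.00187), while OPC-like nuclei lay below it at -0.00225 (simulated from -0.00163).

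In the Visium sections, spots outside the region led by myelin genes, which marks white matter, were summed per section. SHCBP1 (ENSMFAG00000036653), which encodes a protein of signalling and cell division, was higher in both DL sections, at 5.72 CPM in DL6 and 4.75 in DL7, against 0.0286 to 0.142 CPM in the HC and RES sections. The edgeR log2 fold change was 6.005 (SE 0.49, adjusted p = 0.00875) against HC and 5.97 (SE 0.48, adjusted p = 0.00787) against RES. The DL sections held 370 SHCBP1 UMIs and the HC sections 7, a ratio of 66.1 per UMI sequenced (95% exact interval 31.8 to 166, counting error only), and RES sections held 8. It was named after its values were seen, since its mean level lies under the minimum set for named genes. Against HC no gene passed without DL7 (lowest adjusted p of any gene 0.0963), without HC6 (0.129), with only DL and HC in the fit (0.103) or with the replicate number as a block (0.0810), while 4 genes passed without DL6 and 2 without HC7. Against RES no gene passed without RES3, RES4, RES5, DL6 or DL7 (lowest adjusted p from 0.0816 to 0.119). The SHCBP1 log2 fold change in the fits that ended its call was 6.13 (SE 0.59) without DL7, 6.07 (SE 0.62) without HC6, 6.004 (SE 0.50) with only DL and HC, and 6.48 (SE 0.51) with the block, and against RES 5.73 to 6.20 (SE 0.53 to 0.62). Where a group is left with 1 section, that section is assumed to vary like the other groups.

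In RES sections NPTX2, an activity-regulated gene of synapse formation, was at 38.7 to 44.2 CPM against 67.2 to 79.0 CPM in HC (edgeR log2 fold change -0.81, SE 0.10, adjusted p = 0.357). NOV, a secreted matrix protein gene, was at 38.3 to 43.3 CPM against 15.7 to 24.4 CPM (log2 fold change 1.00, SE 0.17, adjusted p = 0.853), and neither gene passed by edgeR, while DESeq2 called both. RES against HC had 0 genes called by edgeR, 550 of 13216 at an unadjusted p under 0.05 and 11 by DESeq2. DESeq2 also called 25 genes in DL against HC and 30 in DL against RES. In lists over the sections, antigen presentation genes were higher in RES than in HC for 11 of 12 members (median log2 fold change 0.67, camera adjusted p = 6.5e-12, and adjusted p = 0.111 with an estimated correlation). In DL against HC they were higher for 9 of 12 (median 0.24, camera adjusted p = 0.0396, and adjusted p = 0.617 with an estimated correlation). Heat shock and chaperone genes were lower in RES than in HC for 15 of 15 (median -0.29, camera adjusted p = 3.8e-12, and adjusted p = 0.119 with an estimated correlation). In DL against HC, where nuclei had lower estimates, the sections gave no call for heat shock genes (7 higher and 8 lower, camera adjusted p = 0.285) or immediate early genes (8 higher and 10 lower, adjusted p = 0.555). In RES against HC the sections had lower estimates for 14 of 18 immediate early genes (median -0.33), 11 of 14 glucocorticoid-response genes (-0.26) and 15 of 19 genes of the unfolded protein response (-0.10), and higher ones for 15 of 19 interferon response genes (0.32). Their camera adjusted p-values were 0.000152, 3.9e-05, 0.00237 and 0.000152, against adjusted p-values of 0.306, 0.111, 0.111 and 0.111 with an estimated correlation. DL against HC also passed for synaptic vesicle genes (17 of 21 higher, camera adjusted p = 0.00492) and for the NF-kB and cytokine response (10 of 12 lower, camera adjusted p = 0.0396), with adjusted p-values of 0.617 and 0.578 with an estimated correlation. Synaptic vesicle genes were higher in DL than in RES for 20 of 21 members (median 0.23, camera adjusted p = 7.3e-06, and adjusted p = 0.489 with an estimated correlation), and so were myelin genes, markers of oligodendrocytes, for 13 of 14 in these spots (median 0.47, camera adjusted p = 0.0242, and adjusted p = 0.640 with an estimated correlation). In the same contrast 13 of 15 heat shock genes and 12 of 19 genes of the unfolded protein response were higher, and 30 of 35 ribosomal protein genes and 11 of 14 reactive astrocyte genes lower, at camera adjusted p-values of 0.000112, 0.0128, 0.000212 and 0.00595 and of 0.489, 0.356, 0.553 and 0.356 with an estimated correlation. Antigen presentation genes, higher in DL than in RES in microglia-like nuclei, were lower in DL than in RES for 11 of 12 members in the sections (median -0.40, camera adjusted p = 0.0128, and adjusted p = 0.489 with an estimated correlation).

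The region led by myelin genes took 10.3% ± 6.14 of spots in HC (SD, n = 3), 13.7% ± 7.92 in RES (n = 3) and a mean of 20.5% in DL (26.5% in DL6 and 14.5% in DL7). The differences were 10.2 percentage points for DL against HC (exact permutation p = 0.3), 3.41 for RES against HC (exact permutation p = 0.6) and 6.78 for DL against RES (exact permutation p = 0.5), in designs too small to go below 0.1. Leaving out RES3 moved the RES difference to -0.289, RES4 to 7.59, HC6 to 0.0209 and HC3 to 6.01. The DL difference from HC was 4.21 without DL6, 16.2 without DL7 and 6.797 without HC6, and that from RES 0.799 without DL6, 12.8 without DL7, 10.5 without RES3 and 2.60 without RES4. With a region needing at least 2 oligodendrocyte markers the differences from HC were -0.690 for DL and -7.47 for RES.

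**Figure D5:**
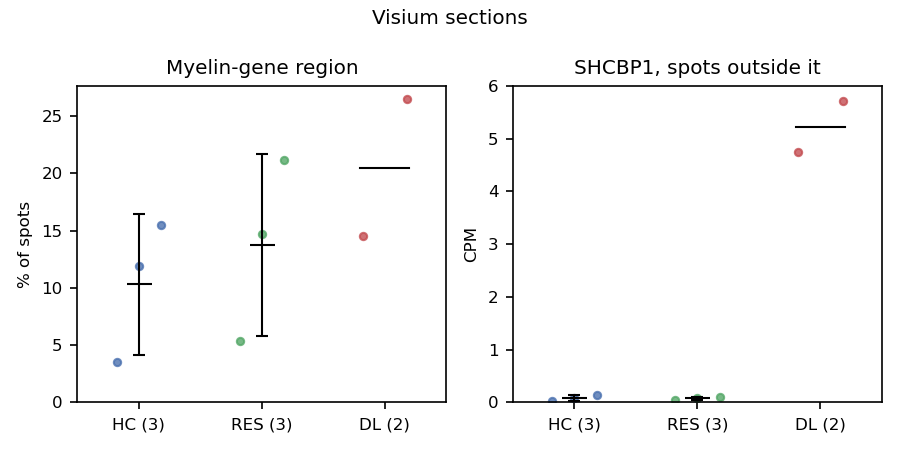
Share of spots in the region led by myelin genes (percent, left) and SHCBP1 in CPM (right), with a point per section, horizontal bars at the means and error bars of 1 SD where a group has 3 sections. SHCBP1 is at 5.72 and 4.75 CPM in DL and at most 0.142 elsewhere.

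The 3 single prefrontal libraries have no replicates, so no test was made, and intervals cover counting error only. Under the limit of 5% mitochondrial UMIs, 186 barcodes remained in HC, 545 in RES and 652 in DL. Microglia-like barcodes were 36.0% of them in HC (95% exact interval 29.1 to 43.4), 89.4% in RES (86.5 to 91.8) and 57.4% in DL (53.5 to 61.2). T cell-like barcodes were 4.84% in HC (2.24 to 8.99), 1.28% in RES (0.518 to 2.63) and 15.3% in DL (12.7 to 18.3). The astrocyte-like share was 28.0% in HC (21.6 to 35.0), 0.460% in DL (0.0950 to 1.34) and 0 of 545 in RES, which allows up to 0.675%. Endothelial-like barcodes were 3.76% in HC, 0.917% in RES and 11.3% in DL. The mitochondrial limit removed 95.5% of HC, 91.2% of RES and 85.6% of DL barcodes with at least 500 UMIs, and the shares moved with it. Without it microglia-like barcodes made up 38.3%, 51.0% and 28.9% in HC, RES and DL, and endothelial-like barcodes 5.56%, 11.5% and 25.5%, so that RES lay above HC. T cell-like barcodes were then 2.48%, 1.51% and 6.26%, and astrocyte-like barcodes 31.3%, 2.87% and 1.30%. Several microglia-like clusters came almost wholly from 1 library, so library and type are not separated there.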

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

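The tests of HC5, of depth, of DL5 and of the individuals numbered 6 and 7 were chosen only after the results were seen, while those of macrophage markers and of free RNA were written before. In 57 tests, each of 1 measure within 1 group of nuclei libraries, 4 single libraries stood apart from the rest of their group. By chance 2.85 would do so, about 1 in 20, if every measure had been picked beforehand. DL3 had 1012 barcodes over the mitochondrial limit against 33 to 298 in the other DL libraries. Inhibitory-like nuclei made up 16.5% in RES1 against 19.9% to 21.2% in the other RES libraries. T cell-like nuclei made up 3.88% in DL5 against 0.173% to 0.672% in the other DL libraries. An excitatory-like cluster held 1597 nuclei of HC5 against 0 to 51 of each other HC library. That cluster was picked because 1 library made up most of it, so this result was fixed in advance and the chance rate does not apply to it.

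Immediate early genes were lower in DL than in HC in excitatory-like nuclei, by -0.316 (SE 0.173) in the mean list score. Without HC5 the difference was -0.225 (SE 0.160), and with the log2 median UMI count as a covariate it was -0.310 (SE 0.164). Each lies within 2 standard errors of 0, as the difference itself does, so neither explanation is excluded. The group difference in behaviour stays open beside them.

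Antigen presentation genes were higher in DL than in HC in microglia-like nuclei, by 1.095 (SE 0.453) in the mean list score. Free RNA from other cells is argued against, since the rise in list UMIs per nucleus in excitatory-like nuclei was 0.0405 of that in microglia-like nuclei (0.00520 to 0.0806 with any 1 library left out). DL5 alone is argued against by a difference of 0.851 (SE 0.414) without it, which is barely over 2 standard errors. More macrophages among these nuclei stay open, since 5 macrophage markers gave a difference of 0.477 (SE 0.315), with mean CPM in HC and DL of 68.3 and 319 for F13A1, 17.1 and 37.0 for LYVE1, 211 and 201 for STAB1, 434 and 257 for CD163, and 647 and 524 for MRC1. The behaviour of the groups stays open as well, untested.

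SHCBP1 was higher in both DL sections, and both came from replicate numbers 6 and 7. Whether a section and a nuclei library of the same number came from the same animal is not established, and the comparison below assumes it. If the individuals rather than the group carried it, the other 5 DL nuclei libraries would lie at the HC level, and their mean difference from HC in excitatory-like nuclei was 0.300 CPM (SE 0.616), which leaves this open. DL6 and DL7 were at 4.99 and 3.93 CPM there, DL3 at 4.05, HC1 at 3.69, HC6 at 1.23 and HC7 at 0.754. All nuclei libraries lay between 0.754 and 4.99 CPM in this class. A group difference as large as that of the sections was therefore not seen in excitatory-like nuclei. Other classes, which the sections also contain, were not compared for SHCBP1 here.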

How the results depend on the processing

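The settings without the 3 doubted libraries, with permuted list scores, without foreign-marker clusters and with sections 6 and 7 alone were chosen only after the results were seen. So were the myelin region with at least 2 markers, the single prefrontal libraries without a mitochondrial limit, and list scores without single libraries. Of the named genes' values 1251 kept direction and side of the threshold, 31 became called and 17 lost a call, 8 of CCNJL and 9 of SHCBP1. For called lists the counts were 114 kept, 145 no longer called and 6 reversed, and 57 of 648 share differences changed sign, with 0 of 27 shares called in each of 24 settings. The cause of the changes below was not tested. In simulated data a log2 change of 1 was recovered for 72.8% of changed genes in excitatory-like, 65.3% in microglia-like and 60.9% in endothelial-like nuclei, and 35.6% in sections (DL against HC). At a log2 change of 0.5 it was 33.9%, 11.5%, 13.2% and 2.74% in the same order. Many genes were changed at once there, in excitatory-like nuclei (DL against HC) 62, 81 and 57 by log2 changes of 0.5, 1 and 2. A gene list was moved besides. Where few genes change, an adjusted p is harder to pass, so a lone changed gene would be recovered less often than these rates. Both points limit what a count of 0 can show.

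DESeq2 called 9 inhibitory-like, 1 oligodendrocyte-like, 1 OPC-like, 8 microglia-like and 1 endothelial-like gene in DL against HC, 7, 1, 1 and 2 in inhibitory-like, oligodendrocyte-like, OPC-like and endothelial-like nuclei in RES against HC, 6 (DL) and 22 (RES, 14 genes) over subclasses, and 25, 11 and 30 in the sections (DL against HC, RES against HC, DL against RES). With no filter, edgeR called 1 gene in microglia-like nuclei (DL), 2 in inhibitory-like, 1 in OPC-like and 1 in endothelial-like nuclei (RES), and 10 (DL) and 7 (RES, 5 genes) over subclasses. DESeq2 size factors gave 1 in subclasses in RES, where the main count was 0. The covariate gave 2 in inhibitory-like nuclei (RES), and leaving out foreign-marker clusters 1. Without the doubted libraries OPC-like nuclei (RES) gave 1 and subclasses 0 (DL) and 3 (RES, 2 genes). With 1 library left out the counts ran from 0 to 1 in excitatory-like (without DL1), microglia-like (HC6) and endothelial-like nuclei (DL2) for DL, from 0 to 2 in inhibitory-like (HC1, HC3, HC5, HC7 or DL2) and 0 to 1 in OPC-like (HC5), microglia-like (HC6) and endothelial-like nuclei (HC2) for RES, from 0 to 2 in subclasses (DL), and in sections from 0 to 4 for DL against HC and 0 to 1 for DL against RES. Only DL and HC in the section fit gave 0, and sections 6 and 7 alone gave 2.

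List counts in DL against HC were 58 without the doubted libraries and 19 without the 2 libraries farthest in median UMIs. In DL against RES these were 25 and 7. The estimated correlation and fry, each with and without those 2 libraries, and permuted scores gave 0 in every contrast. Without the doubted libraries the direction reversed in DL against HC for astrocyte-like glutamate receptors (median log2 fold change 0.0304) and oxidative phosphorylation (0.0312), oligodendrocyte-like ribosomal proteins (0.052) and endothelial-like ribosomal proteins (-0.113). In RES against HC it reversed for excitatory-like ribosomal proteins (0.0243, and -0.0288 without the 2 farthest libraries). Direction here is that of the list test, which can differ in sign from the median.

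The replicate number as a block (a paired design) gave 1 gene in OPC-like nuclei (DL), 1 in inhibitory-like nuclei (RES), 0 in sections (DL against HC), and 39 lists in RES against HC and 10 in DL against RES. The values do not settle whether the numbers pair the libraries. Of 7 HC and DL pairs 6 correlated over 0.1 in excitatory-like and 4 in inhibitory-like nuclei, and 3 and 0 matched their own number best, while of 5 HC and RES pairs 4 correlated and 3 matched in each of these classes. In oligodendrocyte-like and astrocyte-like nuclei 3 and 4 HC and DL pairs correlated over 0.1, and 2 and 1 matched. Of the HC and RES pairs 3 correlated in each of the latter classes, and 1 and 0 matched.

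The myelin region difference with at least 2 markers was -0.690 for DL and -7.47 for RES against HC, and with at least 3 markers the RES difference ran from -0.289 to 7.59 with 1 section left out. Microglia-like shares of the single libraries were 71.2% (HC) and 62.6% (DL) with at least 2000 UMIs, and 51.0% (RES) and 28.9% (DL) without a mitochondrial limit.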

Other observations

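The tests of splits in DL against HC per class and per list, and for the sections, were chosen only after the results were seen, while those for RES against HC, DL against RES and the subclasses were written before. The lists below passed camera with its preset correlation. In DL against HC, 15 of 19 glutamate receptor genes (median log2 fold change 0.21, camera adjusted p = 0.0396, and adjusted p = 0.961 with an estimated correlation) and 15 of 20 voltage-gated channel genes (median log2 fold change 0.29, camera adjusted p = 0.0413, and adjusted p = 0.961 with an estimated correlation) were higher in astrocyte-like nuclei. Scores of the glutamate receptor genes there were 0.748 in DL3 and 0.671 in DL4 against -0.444 in DL1 and -0.374 in DL2, and in microglia-like nuclei 1.18 and 1.24 against -1.19 and -1.04. Without the 3 doubted libraries (HC5, DL3 and DL5) the direction of the glutamate receptor test reversed in astrocyte-like nuclei (camera adjusted p = 0.968) and the voltage-gated channel call ended (adjusted p = 0.593). The difference in the mean glutamate receptor score was 0.167, and 0.0825 without HC5, 0.251 without DL1, 0.0527 without DL3 and 0.0655 without DL4. For voltage-gated channels it was 0.128, and 0.215 without HC3, 0.0752 without HC5, 0.0176 without DL3, 0.0638 without DL4 and 0.194 without DL5. Glutamate receptor genes were higher for 12 of 18 members in OPC-like nuclei (median log2 fold change 0.14, camera adjusted p = 0.0429, and adjusted p = 0.961 with an estimated correlation), a call that ended without the doubted libraries (adjusted p = 0.908), and the score difference went from 0.132 to 0.0538 without HC5. All 11 neuropeptide genes were lower in oligodendrocyte-like nuclei (median log2 fold change -0.54, camera adjusted p = 0.0149, and adjusted p = 0.961 with an estimated correlation), with a score difference of -0.341 that was -0.209 without HC1 and -0.529 without HC4. Immediate early genes were lower for 4 of 5 members in microglia-like nuclei (median log2 fold change -0.30, camera adjusted p = 0.0492, and adjusted p = 0.442 with an estimated correlation), and synaptic vesicle genes for 16 of 19 in endothelial-like nuclei (median log2 fold change -0.13, camera adjusted p = 0.0166, and adjusted p = 0.961 with an estimated correlation). DL2 scored -1.20 for the latter and was also the lowest library there for glutamate receptors (-1.13), GABA signalling (-1.31) and voltage-gated channels (-1.42), and without it the synaptic vesicle score difference went from -0.287 to -0.117. Endothelial-like nuclei numbered 26 in DL1, 31 in DL2 and 24 in DL5, and at least 34 in every other library.

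Oxidative phosphorylation genes, which encode the respiratory chain, were lower in DL in astrocyte-like (25 of 27, median log2 fold change -0.24, adjusted p = 0.961 with an estimated correlation) and oligodendrocyte-like nuclei (23 of 27, -0.28, adjusted p = 0.961 with an estimated correlation). In RES they were lower in astrocyte-like (24 of 27, -0.29, adjusted p = 0.877 with an estimated correlation) and microglia-like nuclei (21 of 24, -0.26, adjusted p = 0.924 with an estimated correlation). HC5 had the highest score of all libraries for these genes in the 3 classes (0.860, 0.616 and 0.729). Without the doubted libraries the direction reversed in DL astrocyte-like nuclei, and the other 3 calls ended (camera adjusted p = 0.414, 0.124 and 0.182 in the order given). The difference in the mean score was -0.177 in DL astrocyte-like nuclei (-0.0555 without HC5, -0.110 without DL3, -0.115 without DL4), -0.217 in DL oligodendrocyte-like (-0.135 without HC5), -0.245 in RES astrocyte-like (-0.123 without HC5) and -0.222 in RES microglia-like nuclei (-0.127 without HC1, -0.122 without HC5, -0.339 without RES2, -0.0937 without RES3). Ribosomal protein genes were lower in DL in oligodendrocyte-like (24 of 30, -0.27, adjusted p = 0.989 with an estimated correlation) and endothelial-like nuclei (21 of 21, -0.39, adjusted p = 0.961 with an estimated correlation). In RES they were lower in excitatory-like (34 of 35, -0.29, adjusted p = 0.924 with an estimated correlation) and oligodendrocyte-like nuclei (26 of 30, -0.29, adjusted p = 0.924 with an estimated correlation). HC5 scored 1.22 for these genes in excitatory-like nuclei, against at most 0.326 in every other HC library, 1.103 in oligodendrocyte-like and 1.102 in endothelial-like nuclei. Without the doubted libraries the direction reversed in both DL classes and in RES excitatory-like nuclei, and the RES oligodendrocyte-like call ended (camera adjusted p = 0.795). The score difference was -0.175 in DL oligodendrocyte-like nuclei (-0.114 without HC1, -0.271 without HC4, -0.0107 without HC5, -0.0959 without DL3, -0.0793 without DL4, -0.274 without DL6), -0.397 in DL endothelial-like (-0.243 without HC5, -0.228 without DL3), -0.133 in RES excitatory-like (-0.0873 without HC1, -0.202 without HC4, 0.0613 without HC5, -0.0870 without RES3) and -0.191 in RES oligodendrocyte-like nuclei (-0.0262 without HC5, -0.115 without RES3, -0.124 without RES4). In the sections ribosomal protein genes were higher in RES than in HC for 34 of 35 members (median log2 fold change 0.14, camera adjusted p = 0.000312, and adjusted p = 0.819 with an estimated correlation). Monoamine receptor genes were lower in RES in excitatory-like nuclei (14 of 18, -0.24, adjusted p = 0.697 with an estimated correlation). Myelin genes were higher in inhibitory-like nuclei (12 of 14, 0.27, adjusted p = 0.924 with an estimated correlation), and immediate early genes were lower in endothelial-like nuclei (7 of 8, -0.37, adjusted p = 0.877 with an estimated correlation). For lists of genes typical of another class, such as these myelin genes, a contribution of free RNA from other cells was not tested. Without the doubted libraries the monoamine receptor call (camera adjusted p = 0.0706) and the endothelial-like call (0.0995) ended. The myelin score difference of 0.192 was 0.116 without HC6 and 0.102 without RES1, and the endothelial-like one of -0.838 was -1.38 without RES1.

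Other splits of the samples gave as many results as the real groups, so chance is not excluded. For lists, 22 of 50 splits gave at least the 31 of DL against HC (highest other split 84), 28 of 50 at least the 18 of RES against HC (highest 61) and 45 of 50 at least the 4 of DL against RES (highest 73). For subclasses 7 of 25 splits gave at least the real count of 1 (highest other 6). For genes per class, where edgeR's real count was 0 throughout (unadjusted and DESeq2 counts stand with each comparison), 50 of 50 splits trivially gave as many. The highest other split reached 34 genes in microglia-like nuclei and 19 genes in endothelial-like nuclei in DL against HC and at most 8 in every other class and contrast. For RES against HC in the sections, 10 of 10 splits gave as many as the real 0 (highest other 0), too few splits for a share under 0.05.

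P3H2, with a small p in microglia-like nuclei, had 0 of 185644 UMIs in microglia-like barcodes of the single HC library, 1 of 1367274 in RES and 2 of 1360223 in DL. Without the mitochondrial limit it had 0 of 6219893 in HC, which allows up to 0.593 CPM, 6 of 10539273 in RES (0.569 CPM, 95% exact interval 0.209 to 1.24) and 8 of 4936936 in DL (1.62 CPM, 0.6996 to 3.19). These single-cell levels are far below those of P3H2 in microglia-like nuclei, at 38.7 CPM in HC, 89.1 in RES and 103 in DL. With so few UMIs in 1 library per group, their order is no independent support for the nuclei. In nuclei, 8.52% of named HC neurons, 8.48% of RES and 8.37% of DL fell in 3 clusters with a single marker of another class among their leading genes.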
